A study of Mus musculus with 6 samples.

How the data were processed

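Total RNA was extracted with Trizol from mouse haematopoietic stem and progenitor cells expressing HoxA9 and Meis1, grown in medium with serum, interleukin-3, interleukin-6 and stem cell factor, and biotinylated cRNA was made from 6 ug of total RNA by the array maker's standard procedure, per the labels' protocols. The probe annotation used here names the array as a whole-transcript mouse gene array of Affymetrix. The deposited table holds 1 processed intensity per probe set and array for 6 arrays, 3 of cells given DMSO and 3 of cells given UNC0638 for 5 days. The summarisation, background correction and normalization that the authors applied, and their software, are not given in the sources used here. From their range of 2.74 to 19527 and medians of 50.4 to 54.9, the values are on a linear scale, their distributions are close but not identical between arrays, and whether they were scaled to a common target stays unknown. Such prior processing can shrink or shift differences, most of all for dim probe sets, so the values were used as deposited and 2 other scalings were tried.

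Of 34760 probe sets, 21640 carry 1 gene symbol in the annotation, 1321 several and 11799 none. Symbols were looked up through the Entrez number in a gene table of the GRCm38.p6 assembly, where 21553 of the single-gene probe sets were found and 0 symbols changed. That table served only for names and for which genes are neighbours, and no coordinates are given because the annotation names no build. Probe sets with several genes or none were left out of the gene tests. Where a gene had more than 1 probe set (954 genes), the one with the highest mean was kept, which gave 19937 genes. Intensities were transformed as log2(value + 16). The pseudocount understates the change of dim genes, so folds are on that scale. Means and SDs of intensities are over the 3 arrays of a group.

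UNC0638 was compared with DMSO in limma 3.58.1 (R 4.3.3) with lmFit and eBayes on group alone, over all 6 arrays, with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05. The estimated prior had 4.47 degrees of freedom. The labels give no batch. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 42 lists with at least 4 measured members, with camera at an estimated correlation and fry alongside. The lists covered H3K9 methylation, the transforming program, myeloid maturation and function, other cell types, immunity, proliferation, stress and survival, metabolism and loci tied to G9a. They held 998 entries, of which 900 matched a measured gene. They stood for 848 distinct genes, 43 of them in more than 1 list, and 36 of the 134 changed genes were in a list and 98 in none. The grouping, the tests, the lists, the alternatives and the rule for named genes were set before the data were examined, except where a choice made later is named as such.

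The genes named are the 12 largest rises and 12 largest falls past the threshold whose groups do not overlap, leaving out symbols of unnamed gene models (3 of the genes that qualified), then Ehmt2, Ehmt1, Hoxa9 and Meis1, and in each list up to 2 rises and 2 falls among members past the threshold, or the member with the largest change where none passed. The rule names 68 genes. Where 5 or fewer members of a list passed, the remaining ones (Pfkl, Ero1a, Egln1, Ltf, Fcnb and Mpeg1) were named after their values were seen, as were the genes named in the closing observations.

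The procedure was tested on simulated data with 200 of 19937 genes changed in 10 simulations of 3 arrays against 3. It found 63.7% of changes of 0.5, 99.6% of changes of 1 and 100% of changes of 2 on the log2 scale, and 5.82% of its calls were false. The simulated noise was normal, with variances already shrunk by eBayes, which vary less between genes than the measured ones. The shares found may therefore be too high for these data, where Scd1 at -1.06 and Atp6v0d2 at 1.71 did not pass. A simulated shift of -0.3 in the interferon list was found in 10 of 10 simulations, with 0 other lists called. The simulated noise was independent between genes, whereas the correlation estimated for the interferon list in the data was 0.23. The simulation therefore does not give the rate of false list calls in these data. The alternatives were quantile normalization, median centring, a filter on the dimmest 40% of genes, other choices among probe sets, a trended robust prior, the replicate number as a block, a threshold of 0.01, array weights, pseudocounts of 1 and 64, other set tests and each array left out in turn. Testing each single-gene probe set was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.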

Results

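Gene expression was measured on Affymetrix arrays in a mouse model of acute myeloid leukaemia, in which haematopoietic stem and progenitor cells had been transformed by the homeobox genes Hoxa9 and Meis1. The cells were treated for 5 days with the solvent DMSO (3 arrays) or with UNC0638 (3 arrays), a small molecule that inhibits the histone methyltransferases G9a (gene Ehmt2) and GLP (gene Ehmt1). The comparison asked which transcripts differ after 5 days of UNC0638 in these cells. It cannot assign a difference to G9a alone, nor tell direct from indirect effects of the compound. Median intensities were 50.4, 51.6 and 52.5 on the DMSO arrays and 53.4, 54.9 and 52.7 on the UNC0638 arrays. The labels number the samples of each group from 1 to 3 but do not say that they were separate cultures, so the p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. Pairwise Pearson correlations were taken over the log2 values of all probe sets, which are not independent replicates. They were 0.985 to 0.987 within DMSO, 0.985 to 0.986 within UNC0638 and 0.980 to 0.987 between the groups. The first principal component over the genes tested held 36.7% of the variance and separated the groups. DMSO arrays were at -14.1, -16.5 and -8.67 and UNC0638 arrays at 9.31, 14.9 and 15.

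After UNC0638, 12 of 30 measured genes of the interferon response fell and 0 rose. The list was called downward by camera with a preset correlation (adjusted p = 4.3e-27) and by fry (0.012), but not by camera with an estimated correlation (0.11). As lists, ribosome biogenesis (2 of 34 genes fell) and glycolysis and hypoxia (5 of 28 fell) were shifted downward, with an adjusted p = 0.022 for each with an estimated correlation. Genes of neutrophil granules and mature neutrophils (4 of 27 rose) were shifted upward as a list (adjusted p = 0.036 with an estimated correlation). Of 19937 genes tested with limma, 134 changed, 74 upward and 60 downward, and 32 of these changed at least 2-fold, 15 upward and 17 downward. With the pseudocount of 16 the largest rise was that of Il22ra2, which encodes a soluble binding protein of interleukin-22. It went from an intensity of 20.01 ± 4.90 to 166 ± 52.7 (SD, n = 3 each, log2 difference 2.31, SE 0.20, adjusted p = 0.00524, probe set 10361906). Clec4b2, a C-type lectin receptor, rose from 84.8 ± 25.7 to 464 ± 91.8 (log2 difference 2.27, SE 0.19, adjusted p = 0.00524, probe set 10541599). Serpinb10, a serine protease inhibitor of haematopoietic cells, rose from 38.4 ± 3.21 to 147 ± 12.7 (log2 difference 1.58, SE 0.090, adjusted p = 0.000604, probe set 10349166). The other large rises were Ms4a8a (1.26), the chemokine receptor Cxcr2 (1.23), the actin-severing protein gene Scin (1.22), and the adhesion molecule Vcam1 (1.18). They were followed by the kallikrein Klk1b11 (1.09), the secreted glutathione peroxidase Gpx3 (1.08), the chitinase-like protein gene Chil3 (1.06), the phosphodiesterase Smpdl3a (1.04) and the arrestin-domain gene Arrdc3 (1.04). Adjusted p ran from 0.00524 for Gpx3 to 0.0469 for Ms4a8a. The largest fall was that of the interferon-induced gene Rtp4, from 733 ± 81.4 to 89.2 ± 26.9 (log2 difference -2.86, SE 0.17, adjusted p = 0.000625, probe set 10434778). This was 7.25-fold lower. Oasl2, also interferon-induced, fell from 311 ± 123 to 57.4 ± 1.09 (log2 difference -2.10, SE 0.22, adjusted p = 0.00859). Ifi206 fell from 140.4 ± 13.8 to 26.6 ± 4.88 (log2 difference -1.88, SE 0.11, adjusted p = 0.000604). Ppbp, the precursor of a platelet chemokine, fell from 1078 ± 254 to 285 ± 34.6 (log2 difference -1.84, SE 0.17, adjusted p = 0.00681). Further falls were those of Usp18 (-1.37), which removes the ubiquitin-like protein encoded by Isg15, Prelid2 (-1.30), the schlafen gene Slfn5 (-1.30), Ifit1 (-1.28), and the collagenase Mmp13 (-1.20). The inducible cyclooxygenase Ptgs2 (-1.18), the mitophagy receptor Bnip3 (-1.17) and the mitochondrial adenylate kinase Ak4 (-1.15) fell too. Adjusted p ran from 0.00681 for Usp18 to 0.0397 for Bnip3. In all 134 genes the 3 arrays of one group lay beyond the 3 of the other, which held for 17% of all genes tested against 10% by chance. Klk1b11, Oasl2, Ifi206, Clec4b2 and Ms4a8a belong to families with similar copies, whose signal the probes could share, and are uncertain to that extent. Leaving out 1 array gave 68, 43 and 69 changed genes without DMSO 1, 2 and 3 and 10, 31 and 40 without UNC0638 1, 2 and 3. In the same order 23, 21, 23, 6, 16 and 21 of the 38 named genes past the threshold kept their call. No sign among the 134 could turn there, since their groups do not overlap. Over 19 alternatives 3 of the 134 calls held in all, those of Rtp4, Ifi206 and Serpinb10, and 55 were lost in at least 10, Ms4a8a (13) and Bnip3 (11) among them. Without each of the 6 arrays in turn, 49 were lost every time. With a pseudocount of 64 the differences were smaller by over 1.5 times for Il22ra2 (1.43), Serpinb10 (1.04), Ifi206 (-1.17), Prelid2 (-0.84) and Ifit1 (-0.77). Clec4b2 was then at 1.83, above Il22ra2, whose mean DMSO intensity lay below the lower quartiles of the arrays (20.9 to 22.8). A joint test of all 34760 probe sets called 4, and centring each array on its median lowered the share of rises among the calls from 55.2% to 43.5%.

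**Figure D1:**
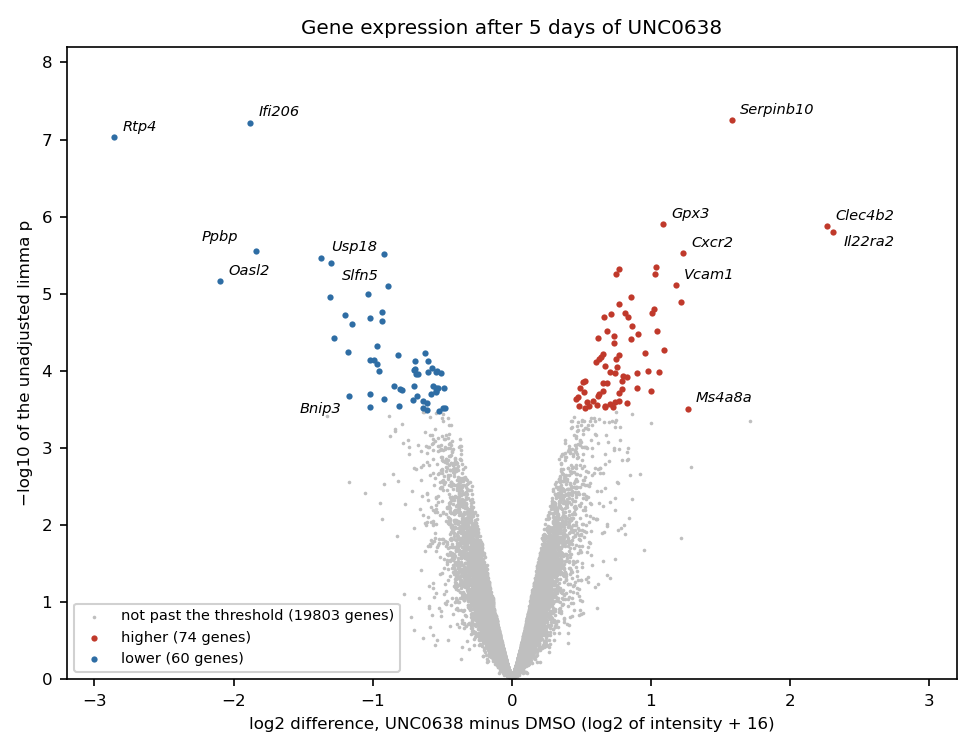
Each point is 1 of 19937 genes, with the log2 difference UNC0638 minus DMSO on the horizontal axis and the negative log10 of the unadjusted limma p on the vertical axis. The 74 genes past an adjusted p of 0.05 that rose are red and the 60 that fell are blue, with Rtp4 at -2.86 and Il22ra2 at 2.31 at the outer ends.

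**Figure D2:**
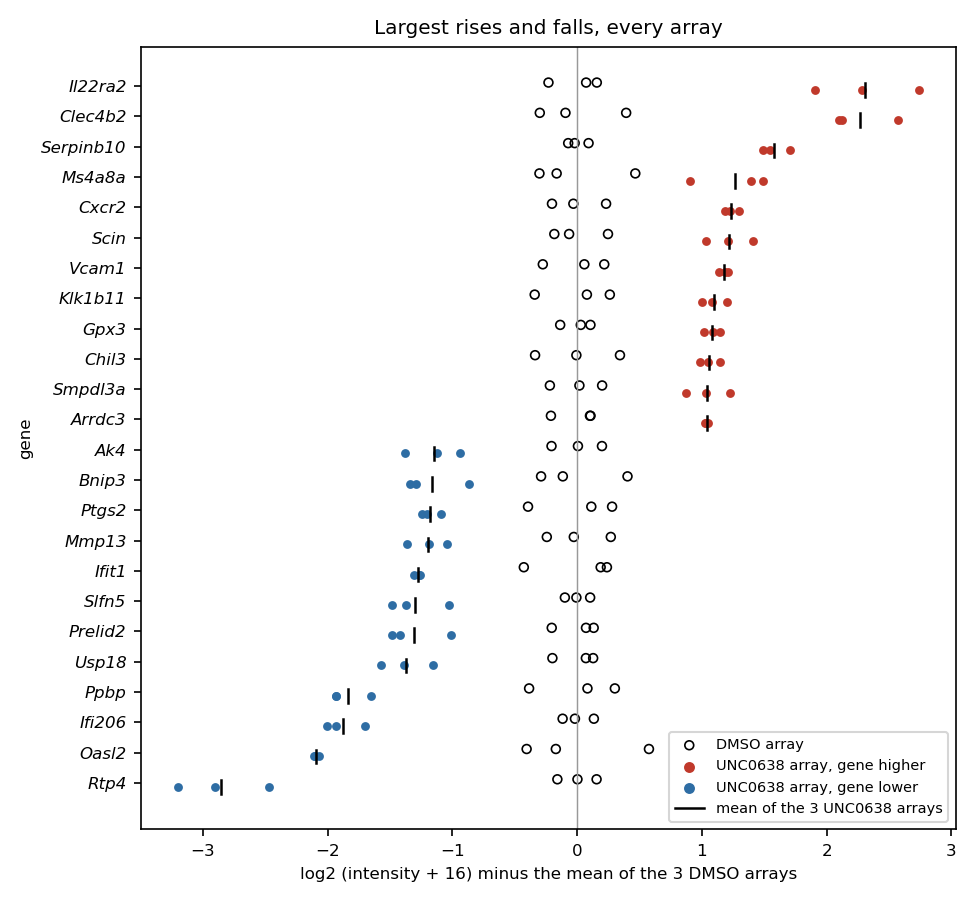
Each row is one of the 12 largest rises or 12 largest falls, and each circle is 1 array, plotted as log2 of intensity plus 16 minus the mean of the 3 DMSO arrays, with DMSO open and UNC0638 filled. The bar is the mean of the 3 UNC0638 arrays, from 2.31 for Il22ra2 to -2.86 for Rtp4, and the 2 groups do not overlap in any row.

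Transcripts of the inhibited enzymes and of the transforming genes did not pass the test. Ehmt2 had an intensity of 123 ± 13.02 in DMSO and 100.6 ± 2.40 in UNC0638 (log2 difference -0.25, SE 0.089, adjusted p = 0.293), and Ehmt1 of 174 ± 12.2 and 169 ± 12.2 (-0.040, SE 0.088, adjusted p = 0.92). Hoxa9 was at 348 ± 28.4 and 319.9 ± 22.4 (-0.12, SE 0.091, adjusted p = 0.686) and Meis1 at 3029 ± 49.6 and 3037 ± 47.9 (0.0036, SE 0.072, adjusted p = 0.993), limma in each case. Hoxa9 and Meis1 were introduced to transform the cells, and the labels do not say whether the probes read the introduced copies. Hoxa9 had a difference of -0.054 without DMSO 1 and -0.068 without UNC0638 3. Ehmt1 lay between -0.093 without UNC0638 2 and 0.0061 without DMSO 2, and Meis1 had one of -0.0095 without DMSO 2, -0.0039 without UNC0638 1, -0.0021 without UNC0638 2 and -0.042 under median centring. Of 25 measured genes of the H3K9 methylation machinery, 0 changed over all genes, 0 did when adjusted over the list alone, and 6 lay at an unadjusted limma p under 0.05. Their median log2 difference was -0.0086 (camera adjusted p = 0.41). The H3K9 methyltransferase Setdb1 was at -0.35 (adjusted p = 0.154). The 10 measured genes of the HoxA cluster had a median of -0.026 (camera adjusted p = 0.83) at a median DMSO intensity of 28.2. That is near the lower quartiles of the arrays (20.9 to 22.8), where the pseudocount shrinks differences, so a response could be missed. Hoxa10 was at 0.18, with 0.306 without UNC0638 1, 0.064 without UNC0638 2 and 0.087 with a pseudocount of 64. In that list 0 genes changed, 0 did when adjusted over the list alone and 0 lay at an unadjusted p under 0.05. The HoxA9/Meis1 leukaemia program, a list of genes known to follow these factors, was shifted upward by a median of 0.10 (camera adjusted p = 0.019, adjusted p = 0.27 with an estimated correlation). Of its 30 genes 0 changed, 1 was lower when adjusted over the list alone, and 7 lay at an unadjusted p under 0.05. Its member Myc had a difference of -0.45 (adjusted p = 0.0807, and 0.0399 with the trended prior). The call was also lost without DMSO 3 (0.10) or UNC0638 2 (0.054), with fry (0.087), with a pseudocount of 1 (0.051) and at the threshold of 0.01.

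Of 30 measured members of the interferon response list, 12 fell and 0 rose, 21 were lower when adjusted over the list alone, and all 30 differences lay below 0, with a median of -0.59. They included Rtp4 and Oasl2 as given above, Usp18, and Ifit1, which encodes an RNA-binding antiviral protein and went from 97.7 ± 26.8 to 29.9 ± 0.764. Of 19 alternatives the call was lost in 8 for Ifit1, 3 for Oasl2, 2 for Usp18 and 0 for Rtp4. Single calls among interferon-related genes were often weak, and Ifit3 and Oas3 lost theirs without each of the 6 arrays in turn. Relative to the DMSO mean, the average of the list was -0.20, 0.086 and 0.11 on the DMSO arrays and -0.70, -0.73 and -0.71 on the UNC0638 arrays. The shift was called by camera with the preset correlation (adjusted p = 4.3e-27) and in 19 of 20 alternatives, among them fry (0.012), and was lost with an estimated correlation (adjusted p = 0.11). The 9 measured genes of class I antigen presentation had a median of -0.091 (camera adjusted p = 0.13). The transactivator Nlrc5 was at 0.25, with 0.14 without UNC0638 2, 0.39 without UNC0638 3 and 0.11 with the mean of its probe sets. The 12 of class II presentation had a median of 0.048 (camera adjusted p = 0.83). H2-DMa was at 0.32. In both lists 0 genes changed and 0 did when adjusted over the list alone, with 0 and 2 at an unadjusted p under 0.05. Among 26 inflammatory cytokines and chemokines, Il1rn, the antagonist of the interleukin-1 receptor, rose from 274 ± 14.5 to 425 ± 30.9 (log2 difference 0.61, adjusted p = 0.0261). It was the 1 member that passed, a call lost in 9 of 19 alternatives, with 1 higher and 1 lower when adjusted over the list alone, and the median of that list was 0.12 (camera adjusted p = 0.41).

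Of 34 measured genes of ribosome biogenesis and Myc targets, 2 fell, 25 were lower when adjusted over the list alone and 33 lay below 0. They had a median log2 difference of -0.39 (camera adjusted p = 1.8e-24, and adjusted p = 0.022 with an estimated correlation). Nolc1, which encodes a nucleolar chaperone of small nucleolar ribonucleoproteins, fell from 957 ± 74.9 to 650.1 ± 20.9. Gnl3, a nucleolar GTPase gene, fell from 954 ± 49.6 to 675 ± 9.73, both with an adjusted p of 0.0363. These calls were lost in 12 and 10 of 19 alternatives. In the list of glycolysis and hypoxia, 5 of 28 genes fell, 16 were lower when adjusted over the list alone. The median was -0.32 (camera adjusted p = 3.1e-15, and adjusted p = 0.022 with an estimated correlation). The 5 were Bnip3 (1434 ± 378 to 623 ± 119), Higd1a (-0.61), Pfkl (-0.55), the liver-type phosphofructokinase, Ero1a (-0.55), an oxidase of the endoplasmic reticulum, and Egln1 (-0.51), the oxygen-sensing prolyl hydroxylase. Of 19 alternatives the call was lost in 11 for Bnip3, 16 for Higd1a, 12 for Pfkl and 10 each for Ero1a and Egln1, and Higd1a, with an adjusted p of 0.0487, was at -0.34 with the mean of its probe sets. All 11 genes of serine and glycine synthesis lay below 0, and 0 fell over all genes tested. Adjusted over the list alone 8 were lower, the same number as at an unadjusted p under 0.05 (median -0.34, camera adjusted p = 7.5e-09, adjusted p = 0.11 with an estimated correlation). The mitochondrial enzyme Shmt2 was at -0.61 (adjusted p = 0.201).

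Of the cell cycle and other metabolic lists, 4 were called downward with the preset correlation, none of them with a member past the limma threshold over all genes. For G1/S and DNA replication the median of 31 genes was -0.22 (camera adjusted p = 1.4e-10, adjusted p = 0.11 with an estimated correlation). Of these genes 6 were lower when adjusted over the list alone. The clamp loader subunit Rfc4 was at -0.50 (adjusted p = 0.0567, and 0.0474 with the filter on dim genes). For G2/M and mitosis the median of 31 genes was -0.12, and 0 passed when adjusted over the list alone (camera adjusted p = 4.6e-05, adjusted p = 0.25 with an estimated correlation). The mitotic activator Cdc20 was at -0.38. Oxidative phosphorylation had a median of -0.14 over 33 genes, of which 0 passed when adjusted over the list alone (camera adjusted p = 1e-06, adjusted p = 0.23 with an estimated correlation). The complex III subunit Uqcrc1 was at -0.39. Fatty acid synthesis had a median of -0.11 over 14 genes, of which 3 were lower when adjusted over the list alone (camera adjusted p = 0.0047, adjusted p = 0.23 with an estimated correlation). The desaturase Scd1 was at -1.06 (adjusted p = 0.138, and 0.0258 with the replicate block). At an unadjusted p under 0.05 these 4 lists held 14, 9, 5 and 5 genes. With fry, G1/S and DNA replication was called (adjusted p = 0.015). G2/M and mitosis (0.082), oxidative phosphorylation (0.087) and fatty acid synthesis (0.061) were not. Lists that were not called were cholesterol synthesis and uptake (median -0.10, camera adjusted p = 0.12, Pmvk at -0.50), histone genes (median 0.032, 0.51, H2bc21 at 0.57) and cyclin-dependent kinase inhibitors (median -0.010, mean 0.047, 0.80 upward, Cdkn1b at 0.46, with 0.25 without DMSO 2 and 0.30 with the mean of its probe sets). In these 3 lists 0 genes changed, 2 lower, 1 higher and 0 passed when adjusted over the list alone, and 4, 3 and 2 lay at an unadjusted p under 0.05. Autophagy was not called either (median 0.054, camera adjusted p = 0.78), and its member Bnip3 fell, the 1 gene that passed over all genes and when adjusted over the list alone.

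Of 27 measured genes of secondary and tertiary neutrophil granules and mature neutrophils, 4 rose, 0 fell and 8 were higher when adjusted over the list alone. The shift was called (median 0.24, camera adjusted p = 1.5e-08, and adjusted p = 0.036 with an estimated correlation). Cxcr2, the receptor that draws neutrophils to chemokines, rose from 262 ± 42.6 to 632 ± 25.6 and Chil3 from 1138 ± 271 to 2348 ± 138. The other 2 were Ltf (0.77), which encodes the granule protein lactoferrin, and Fcnb (0.48), a ficolin. Of 19 alternatives the call was lost in 2 for Cxcr2, 8 for Chil3, 11 for Ltf and 15 for Fcnb. In the monocyte and macrophage list, 3 of 29 genes rose, and 14 were higher and 2 lower when adjusted over the list alone. The shift was called (median 0.36, camera adjusted p = 5e-08), but not with an estimated correlation (adjusted p = 0.25) or with fry (0.065). These were the integrin Itgax (48.4 ± 4.37 to 93.7 ± 6.09), the glycoprotein gene Gpnmb (1426 ± 213 to 2266 ± 95.1) and Mpeg1 (0.51), a pore-forming protein of macrophages. These calls were lost in 3, 14 and 11 of 19 alternatives, and Itgax went from 0.77 to 0.49 with a pseudocount of 64. Myeloid transcription factors had a median of 0.17 over 32 genes (camera adjusted p = 4.6e-05, adjusted p = 0.27 with an estimated correlation). Over all genes 0 changed, and 4 were higher when adjusted over the list alone. The immediate early gene Fos was at 0.57 (adjusted p = 0.0596, and 0.0408 with the filter on dim genes). Lysosomal genes had a median of 0.11 over 36 genes (camera adjusted p = 8.5e-05, adjusted p = 0.25 with an estimated correlation). Again 0 changed, and 4 were higher when adjusted over the list alone. The proton pump subunit Atp6v0d2 was at 1.71 (196 ± 109 to 628 ± 113, adjusted p = 0.0567). It passed without DMSO 1 (0.00902), with the filter on dim genes (0.0166), with the trended prior (0.0448) and with a pseudocount of 1 (0.0284). At an unadjusted p under 0.05 these 2 lists held 8 and 11 genes. With fry neither list was called (adjusted p = 0.084 and 0.058). In the list of phagocyte oxidase and respiratory burst, Ptgs2 fell while 9 of 10 genes lay above 0, and 2 were higher and 1 lower when adjusted over the list alone. The shift was called (median 0.14, camera adjusted p = 0.039, adjusted p = 0.23 with an estimated correlation). That call was lost in 11 of 20 alternatives. Besides the estimated correlation these were fry (0.063), the filter on dim genes (0.064), the trended prior (0.069), the replicate block (0.061), a pseudocount of 1 (0.13) and the threshold of 0.01. The others left out DMSO 1 (0.11), DMSO 2 (0.062), DMSO 3 (0.081) or UNC0638 1 (0.25). Primary granule genes of promyelocytes were not called (median -0.016, mean 0.082, camera adjusted p = 0.39 upward). However, Nkg7, a granule membrane protein gene of cytotoxic cells, rose from 1558 ± 129 to 2953 ± 549 (log2 difference 0.90, adjusted p = 0.0285, a call lost in 9 of 19 alternatives), and 3 of its list were higher when adjusted over the list alone.

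**Figure D3:**
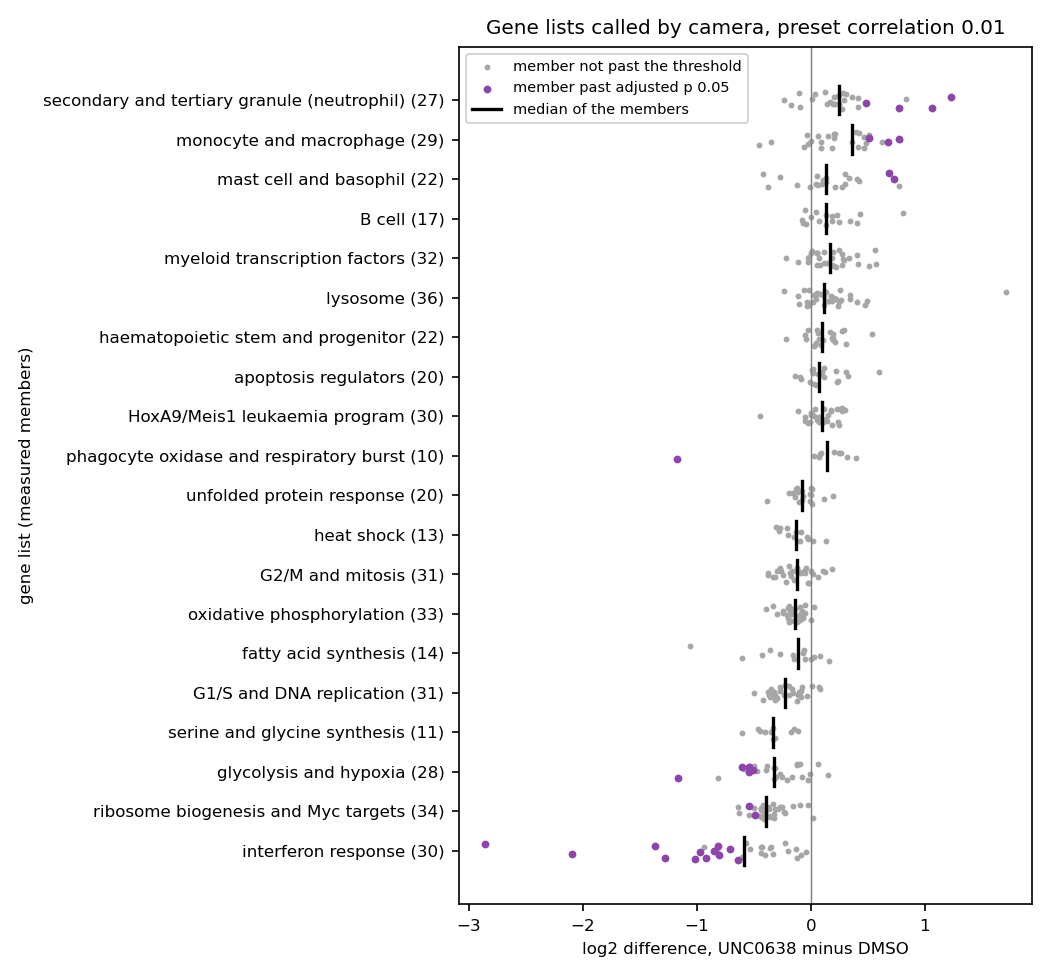
Each row is one of the 20 gene lists called by camera with a preset correlation of 0.01, with the number of measured members in brackets, and each point is a member at its log2 difference UNC0638 minus DMSO. Purple points passed an adjusted p of 0.05 over all genes and black bars are list medians, from -0.59 for the interferon response to 0.36 for monocyte and macrophage genes.

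Markers of other blood cell types were measured beside the myeloid lists. Of 22 mast cell and basophil genes, the mast cell proteases Cma1 (230.0 ± 21.5 to 392.1 ± 23.1) and Tpsb2 (324 ± 21.05 to 531 ± 31.6) rose, calls that were lost in 6 and 7 of 19 alternatives. Adjusted over the list alone, 7 were higher and 1 lower (median 0.13, camera adjusted p = 0.0015, adjusted p = 0.11 with an estimated correlation). B cell genes had a median of 0.13 over 17 genes at a median DMSO intensity of 41.2 (camera adjusted p = 0.0046, adjusted p = 0.12 with an estimated correlation). Over all genes 0 changed, and 4 were higher when adjusted over the list alone. The interleukin-7 receptor gene Il7r was at 0.81, and at 0.49 without DMSO 2. Genes of haematopoietic stem and progenitor cells had a median of 0.094 over 22 genes (camera adjusted p = 0.0052, adjusted p = 0.12 with an estimated correlation). In this list 0 changed over all genes and 0 when adjusted over the list alone. The growth factor gene Angpt1 was at 0.53. At an unadjusted p under 0.05 the B cell and progenitor lists held 5 and 4 genes. Lists that were not called were eosinophil (median 0.11, camera adjusted p = 0.11, Siglecf at 0.83), T and NK cell (median 0.031, 0.17) and erythroid (median 0.021, 0.51). The same held for dendritic cell (median 0.065, mean -0.013, 0.57 upward), megakaryocyte and platelet (median 0.033, mean -0.13, 0.74 downward) and fibroblast and stroma (median 0.016, mean -0.020, 0.81 upward). Adjusted over the list alone, 2 eosinophil genes were higher and 1 lower, with 0 over all genes and 3 at an unadjusted p under 0.05. Between 1 and 2 genes passed in each of the other lists. Single members of these passed over all genes. The granzyme Gzmb (0.52), the carbonic anhydrase Car1 (0.96) and the smooth muscle actin Acta2 (0.80) rose, and Bst2 (-0.92), an interferon-induced restriction factor placed in the dendritic list, and Ppbp fell. Of 19 alternatives the call was lost in 12 for Gzmb, 8 each for Car1 and Acta2, 11 for Bst2 and 2 for Ppbp, and Car1 was at 0.57 with a pseudocount of 64. Siglecf, with an adjusted p of 0.0807, passed without DMSO 1 (0.0402), with the filter on dim genes (0.0379) and with the trended prior (0.045).

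Heat shock genes had a median of -0.13 over 13 genes (camera adjusted p = 0.0092, adjusted p = 0.27 with an estimated correlation). The cochaperone Chordc1 was at -0.30, and at -0.18 without UNC0638 2. The call was also lost without DMSO 3 (0.16) and with fry (0.16). The unfolded protein response had a median of -0.078 over 20 genes (camera adjusted p = 0.039, adjusted p = 0.25 with an estimated correlation). The chaperone Hyou1 was at -0.38. Its call was lost in 11 of 20 alternatives. Besides the estimated correlation these were quantile normalization (0.52), the filter on dim genes (0.23), the replicate block (0.061), array weights (0.061), a pseudocount of 1 (0.079), fry (0.087) and the threshold of 0.01. The others left out DMSO 1 (0.23), UNC0638 2 (0.11) or UNC0638 3 (0.16). Apoptosis regulators had a median of 0.070 over 20 genes (camera adjusted p = 0.031, adjusted p = 0.23 with an estimated correlation). The pro-apoptotic Bcl2l11 was at 0.60 (adjusted p = 0.0567, and 0.0362 with the filter on dim genes). The call was also lost without DMSO 2 (0.074), DMSO 3 (0.054) or UNC0638 1 (0.11), with the trended prior (0.054), with a pseudocount of 1 (0.062) and at the threshold of 0.01, and was kept by fry (0.012). No member of these 3 lists passed over all genes, 0, 0 and 1 did when adjusted over the list alone, and 2, 1 and 5 lay at an unadjusted p under 0.05. The NRF2 oxidative stress list (median 0.10, camera adjusted p = 0.23, Hmox1 at 0.43) and p53 targets (median -0.084, 0.56, Fas at 0.44) were not called. In these 0 genes changed, 1 and 2 were higher when adjusted over the list alone, and 6 and 5 lay at an unadjusted p under 0.05. Hmox1, with an adjusted p of 0.0567, passed with quantile normalization (0.0446) and array weights (0.0485). The list of ATF4 and the integrated stress response was not called either (median -0.041, mean 0.0052, camera adjusted p = 0.39 downward). The stress-induced transcription factor gene Atf3 rose from 421 ± 86.2 to 851 ± 129 (log2 difference 1.00, adjusted p = 0.0377), a call lost in 9 of 19 alternatives. In that list 1 gene was higher and 1 lower when adjusted over the list alone.

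Loci on which G9a is known to act were not called as lists. Germline genes had a median of 0.038 over 37 genes at a median DMSO intensity of 23.3 (camera adjusted p = 0.31), with Tuba3b at -0.30. Imprinted genes had a median of 0.037 over 30 genes (0.74), with Dlk1 at -0.40, and embryonic globin genes had a median of 0.052 over 4 genes (0.39), with Hbb-y at 0.18. The median DMSO intensity was 36.3 for imprinted and 26 for embryonic globin genes. All 3 lists were thus dimmer than the array medians (50.4 to 54.9), where the pseudocount shrinks differences, so a response could be missed. In these 3 lists 0 genes changed and 0 did when adjusted over the list alone, with 1, 1 and 0 at an unadjusted p under 0.05. Tuba3b was at -0.17 without DMSO 2, -0.14 without UNC0638 3, -0.59 with a pseudocount of 1 and -0.12 with one of 64. Hbb-y was at 0.079 without UNC0638 1, 0.309 without UNC0638 2, 0.28 with a pseudocount of 1 and 0.086 with one of 64. Of the 42 lists, 20 were called with the preset correlation, 10 upward and 10 downward. The calls for ribosome biogenesis, glycolysis and hypoxia, and neutrophil granules held with an estimated correlation. fry, which tests whether the genes of a list move on balance one way without comparing them with other genes, called 10 of the 20. For each called list but the unfolded protein response (up to 0.52) and phagocyte oxidase (up to 0.25), the p with an estimated correlation was the highest over 20 alternatives. The medians of 8 of the 22 lists that were not called changed sign under quantile normalization or median centring, and 0 of the 20 called ones did. Median centring moves every list by the same amount, and the called lists had been picked for their shift, with medians at least 0.070 from 0. This contrast is therefore no support for the calls.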

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

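The tests on single DMSO arrays, on scaling and on paralogs for the interferon genes and the test of a larger neutrophil share were chosen after the results were seen, while the splits of the arrays and the intensity trend were chosen before.

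A probe set outside the gene comparison stood out. Probe set 10608282, annotated with several genes so that none is named, had an intensity of 5.37 ± 0.914 in DMSO and 33.5 ± 2.51 in UNC0638 (SD, n = 3 each), a log2 difference of 1.21 (SE 0.077, limma adjusted p = 0.0235 over all 34760 probe sets). The DMSO value lies near the lowest intensities of the arrays (2.74 to 2.98) and below their lower quartiles (20.9 to 22.8), so the size of the rise is uncertain. It was the 1 of 1321 probe sets with several genes that passed, and of 11799 probe sets without a gene 0 passed in limma, with 1186 at an unadjusted p under 0.05.

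There are 10 ways to part the 6 arrays into 3 and 3, which is too few for a share under 0.05. The real split gave 134 changed genes and the highest of the others 1, so that 1 of the 10 splits, the real one, gave a count as large. For rises the real count was 74, for falls 60 and for changes of at least 2-fold 32. In the other splits the larger of the 2 directions held at most 1 gene, and at most 1 gene changed at least 2-fold. The real split called 20 gene lists and the others 1 to 10, so camera with the preset correlation called lists in each mixed split too. The 2 sides of a mixed split hold unequal numbers of UNC0638 arrays, so part of the difference between the groups remains. The lists called there therefore do not give a rate of false calls.

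Interferon-induced genes were lower after UNC0638, with a mean log2 difference of -0.71 over 30 genes and a call of the list with the preset correlation and by fry (adjusted p = 0.012) that was lost with an estimated correlation (0.11). A single DMSO array with raised interferon genes would leave a mean above -0.36 once that array is left out, and the value nearest 0 was -0.66. Array scaling is argued against by a mean of -0.72 at its nearest to 0 under quantile normalization and median centring. Signal shared between paralogs is argued against by -0.74 with 1 gene per family, over 21 genes. A lower interferon tone under inhibition of G9a and GLP is therefore a candidate explanation, as a hypothesis found on the same data and not itself tested. A difference in culture handling between the groups was not tested either.

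Genes of neutrophil granules and mature neutrophils were higher, with a mean of 0.29 over 27 genes. A bias that depends on intensity is argued against, since the mean was 0.32 after the trend over intensity was removed. A larger share of mature neutrophils stays open and cannot be told apart from a change within the cells. The 6 brightest members (Lyz2, Mmp8, S100a9, S100a8, Ngp and Pglyrp1) had a median of 0.22, near the 0.24 of the whole list. The members past the threshold had a median of 0.92, but they had been picked for large differences. That contrast therefore does not show that the brightest members rose less. With DMSO intensities from 2130 upward, the high baseline of the 6 brightest would also hide a small added share.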

How the results depend on the processing

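Each alternative was planned except the test of single-gene probe sets, which was chosen after seeing the data. All 134 calls kept their sign in each of the 19 gene-level alternatives in which they were tested, and 0 of the 38 named genes past the threshold turned. Since the groups do not overlap in these genes, only other scalings or another choice among probe sets could have turned a sign. In the remaining alternatives the kept sign is no support. Rtp4, Ifi206 and Serpinb10 kept their call in all 19. Counts of changed, higher, lower and at least 2-fold changed genes were 134, 74, 60 and 32. The first 3 moved by over 1.5 times in 10 of 19 alternatives, namely the joint test, the threshold of 0.01, the pseudocount of 64, the replicate block and each left-out array, and the 2-fold count in 6, not with the replicate block or without a DMSO array. A joint test of every probe set gave 4, 2, 2 and 4, counted in probe sets, and a threshold of 0.01 gave 18, 10, 8 and 14 genes. A pseudocount of 64 gave 49, 32, 17 and 8, and leaving out 1 array gave 10 to 69, 7 to 42, 3 to 31 and 8 to 30. For the threshold the stricter limit gives the cause. Leaving out an array leaves fewer samples, but the count also depended on which array it was. It was 10 without UNC0638 1 and 69 without DMSO 3, and the cause of that spread was not tested. For the pseudocount the cause was not tested. In the joint test, probe sets without a gene were noisier (median residual SD 0.187 against 0.121 for genes) and the prior fell from 4.47 to 2.51 degrees of freedom. With single-gene probe sets alone the counts, again of probe sets, were 102, 57, 45 and 30. The labels do not say whether the replicate numbers pair the samples, and the arrays do not settle it. Deviations of same-numbered arrays correlated at -0.062, 0.11 and 0.017, and 1 of 3 UNC0638 arrays correlated best with its own number. The replicate block gave 73, 43, 30 and 31. With it 62 of the 134 calls were kept, and 28 of those of the 38 named genes. Filtering the dimmest 40% of genes gave 193, 109, 84 and 34, and the trended robust prior 180, 106, 74 and 34. Scaling changed less, with quantile normalization at 128, 76, 52 and 31 and median centring at 115, 50, 65 and 30, the last with 43.5% of calls upward against 55.2%. Small differences reversed without a call. These were Ehmt1 without DMSO 2 (0.0061, in a range of -0.093 to 0.0061 over left-out arrays) and Meis1 (-0.0095 to 0.017) under median centring (-0.042) and without DMSO 2 (-0.0095), UNC0638 1 (-0.0039) or UNC0638 2 (-0.0021), and the cause was not tested. Of 42 lists, 20 were called, 3 with an estimated correlation, 10 by fry, 20 by camera on ranks and 17 to 19 without 1 array, and the cause of the loss was not tested. Ribosome biogenesis (adjusted p up to 0.022), glycolysis and hypoxia (up to 0.022) and neutrophil granules (up to 0.036) kept their call in all 20 alternatives, the interferon response in 19, and phagocyte oxidase and the unfolded protein response in 9 each. The test of every probe set was not run on gene lists. Signal over background limits the dim genes, since no detection calls were used and the pseudocount of 16 shrinks their differences.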

Other observations

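The tests of gene families, of dim genes under other scalings and of the odds ratio were chosen after the results were seen, while those of neighbouring genes and of the dim share were chosen before.

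Of 589 gene families grouped by the stem of their symbol, camera with the preset correlation called 53, 45 downward and 8 upward, and 0 with an estimated correlation, where the families named here had adjusted p from 0.54 to 0.95. Without each array in turn 30 of the 53 kept their direction and call, and those of the stems Rpl and Rps did not. These stems hold cytoplasmic ribosomal proteins but also other genes, such as the kinase gene Rps6ka3. Mitochondrial ribosome proteins (Mrpl) lay below 0 in 43 of 48 genes (median -0.21, adjusted p = 4.6e-11), and Mrpl12 fell by 0.56, a call lost in 11 of 19 alternatives. Nucleoporins (Nup) lay below 0 in 19 of 20 (median -0.22), RNA exosome subunits (Exosc) in 9 of 9 (median -0.32) and proteins of the proteasome and its assembly (Psmd) in 14 of 14 (median -0.19). The schlafen family (Slfn), whose members are interferon-induced in part, lay below 0 in 9 of 9 genes, and Slfn5 (-1.30), Slfn1 (-0.99) and Slfn8 (-0.64) fell, calls lost in 2, 8 and 13 of 19 alternatives. Among families above 0 were the Toll-like receptors (Tlr, median 0.40 over 10 genes), of which Tlr1 rose (0.83, a call lost in 12 of 19 alternatives), and the C-type lectins (Clec, 28 of 33 above 0), of which Clec4b2 rose. Under quantile normalization and median centring 0 of the 53 medians changed sign, but these families had been picked for their shift, so this is no support.

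G9a is known to act on domains that hold several genes, and the hypothesis was that genes that rose would be neighbours. Of 74 genes that rose, 2 (Olfr460 and Mgam) had another such gene among the 5 tested genes on either side. In 10000 random lists matched on intensity the median was 2 and the upper limit 8 (permutation p = 0.78, 1-sided). The prediction was not met among these genes. A count inside the range of random lists cannot exclude such domains, since the power to detect them was not estimated. Of 60 genes that fell, 9 had another fallen gene that near, against a median of 2 and an upper limit of 6 (permutation p = 0.0032, 1-sided). These were Ifi203 and Ifi205, Slfn1, Slfn5 and Slfn8, Ifit1 and Ifit3, and Oas2 and Oas3, which are clusters of interferon-related paralogs.

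If inhibition of G9a released silent genes, genes that rose would be dimmer than genes that fell. Among called genes, 5 of 74 rises and 3 of 60 falls lay in the dimmest 40% of genes (Fisher's exact test, 2-sided, p = 0.73). The odds ratio was 1.37 with a 95% interval of 0.255 to 9.22, which holds both no difference and the 4.11 found among genes at an unadjusted p under 0.05. A p above 0.05 was therefore too weak a criterion against release, and the question stays open. At an unadjusted limma p under 0.05, 20.7% of 1290 rises and 5.97% of 1239 falls were dim as deposited. These shares were 11.4% and 12.5% after quantile normalization, 14.4% and 9.48% after median centring and 14.6% and 3.78% with a pseudocount of 64. The excess among rises was gone after quantile normalization and smaller after median centring, so array scaling at low intensities stays open as its cause.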
